A study of Mus musculus with 38 samples.

How the data were processed

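Intestinal stem cell organoids of C57BL6 mice were grown from crypts for 8 days over 2 passages in 65% matrigel, with 1 uM GW501516 or with 0.1% DMSO as vehicle, per the labels' protocols. GW501516 (GW) is a synthetic agonist of the nuclear receptor PPARδ, which Ppard encodes. The samples came from wild-type mice (WT), from Ppard knockouts (D), from Ppara knockouts (A) and from knockouts of both genes (DA). Ppara encodes the related receptor PPARα. The labels write the Ppard genotype as floxed and the Ppara genotype as null, and they name no recombinase. RNA was taken with TRI reagent, and polyadenylated RNA was profiled by high-throughput 3′ digital gene expression, which reads tags from the 3′ end of transcripts.

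Of the 38 samples, 37 had a group, in 8 groups of 4 genotypes by treatment. The remaining sample was unassigned because its title named GW in D while its genotype label named both genes. The tables held 57 columns, of which 37 were used. Columns were joined to groups by the treatment and genotype in their names, and no column carried a replicate number, so replicates here are numbered in column order within a group. The 20 columns not used were 19 with the letters KD, which no sample's title holds, and 1 of the 4 columns named GW in D. Which of those 4 columns belonged to the unassigned sample could not be told from the names, so it may be among the 3 used. 4 used columns carried a suffix 2 that no label explains.

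The authors deposited whole-number counts per Ensembl gene, and a second table of log2 values. By the values, the deposited log2 table holds log2 of the normalised count CPM (a library's counts scaled to sum to 1e+06) plus 1. Its back-transformed values sum to 1e+06 in each library and, at the library's total, lie within 0.5 of the counts. Only 90.5% of its nonzero back-transformed values lay within 0.01 of a whole count, so the deposited counts were rounded estimates. Per the submitters' processing notes, Salmon 1.1.0, R 3.6.2, edgeR 3.26.8 and the mouse build mm10 were used. The notes give no annotation release, no handling of molecular identifiers and no filter. Symbols, positions and gene types were taken from the GENCODE annotation of the same build, in which 54109 of the 54352 Ensembl identifiers had a symbol and 243 had none.

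Total counts per library ran from 353347 to 577557, with a median of 483848. A count of 0 allows up to 3 counts, taken here over a group, and such floors and intervals cover counting error only. No 2 libraries of the same group were copies: in each of the 69 within-group pairs the counts differed by more than sampling, with a chi-square per degree of freedom from 1.51 to 7.10 over genes with at least 10 counts. The lowest were between replicates 4 and 5 of vehicle in WT, D and A and of GW in A (1.51, 1.81, 1.86 and 2.00). Those of GW in WT and in DA had 3.28 and 2.61. A test for copies cannot tell repeat preparations of the same animal or culture from separate ones.

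Genes with too few counts were removed with edgeR's filterByExpr by group, which left 4902 genes. Counts were scaled with TMM and fitted over all 8 groups in 1 model with edgeR 4.0.16 (glmQLFit and glmQLFTest) under R 4.3.3. Values were adjusted by Benjamini-Hochberg within each comparison, and a gene passed at an adjusted p of 0.05. The comparisons, the tests, the gene lists and their alternatives were chosen before the data were examined, with the exceptions given here. There were 12 such comparisons: GW against vehicle in each genotype, the difference of that response between genotypes, and each knockout against WT in vehicle. The knockouts against WT under GW, and the mean GW effect over the 4 genotypes, were added after the data were examined. Differences between genotypes averaged over both treatments were also looked at and are not reported. The p-values measure only the spread between libraries, since the labels do not say whether libraries came from separate animals or cultures.

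Gene lists for metabolic pathways, cell types and stress responses were tested with limma 3.58.1 camera on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Lists with at least 3 measured members were tested, which left 26, and adjustment was over these within a comparison. Each call is given with its adjusted p under an estimated correlation. Where a list is described, its members that passed are counted over all genes and adjusted over the list alone. The genes in the text follow a fixed rule. Ppara, Ppard and Pparg were reported in every group. Among genes that passed with a mean log2 CPM of at least 4, up to 12 of the largest increases and 12 of the largest decreases could be named, leaving out predicted genes. Up to 4 members with the smallest p could be named per list. Cpt1a, Pdk4, Angptl4, Plin2, Acadvl, Acaa2, Fabp1, Lgr5 and Olfm4 were reference genes for the GW effects, whatever their p. Some genes, and 1 list with its members, are counted in the totals but are not reported here. Genes outside this rule are marked as chosen after their values were seen.

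The analysis was tested on simulated counts with the depth and spread of these libraries, in 5 simulations with 200 changed genes each. In WT, 24.4% of genes changed 1.5-fold, 59.6% of those changed 2-fold and 93.6% of those changed 4-fold were recovered. In D, with 3 GW libraries, the shares were 9.20%, 47.2% and 87.2%. For the difference between DA and WT they were 4.00%, 25.6% and 75.2%. Unchanged genes made up 4.16% to 5.56% of the calls, and a fatty acid oxidation list shifted 1.5-fold was called in 5 of 5 simulations of each comparison tried. The simulated genes and libraries varied independently, without correlated genes or any structure of the libraries beyond their groups. These shares may therefore not carry over to the data.

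The alternatives planned were RLE size factors, no filter on low counts, only the groups compared in the fit, DESeq2 1.42.0, limma-trend on the deposited log2 CPM, fry for lists, an estimated correlation, and leaving out each library in turn. Others were added after the libraries were seen to split by the numbers in their column names. They were a block for the 6 runs of library numbers, a block for the class of Xist or Y-linked counts, fits to libraries 1 to 36 or 37 to 60 alone, and a fit without the columns with the suffix 2. Other splits of the libraries were drawn, up to 100 per comparison, and fitted without and with the block for library numbers.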

Results

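The 37 libraries measured polyadenylated RNA of intestinal stem cell organoids from wild-type mice (WT) and from knockouts of Ppard (D), of Ppara (A) or of both genes (DA). They were grown with the PPARδ agonist GW501516 (GW) or with DMSO vehicle. There were 5 vehicle and 5 GW libraries in WT, 5 and 3 in D, 5 and 5 in A, and 4 and 5 in DA. Total counts were 353347 to 577557 per library, and 9660 to 11085 genes had a count. Group medians ran from 446699 for GW in WT to 513028 for vehicle in D. Mitochondrially encoded transcripts took 7.55% to 10.6% of the counts. An additional sample had no clear genotype and was given no group, and its column was not ruled out among the 3 used for GW in D.

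The libraries also separated by the numbers in their column names. The first principal component, with 13.0% of the variance, parted the 23 libraries numbered 1 to 36 from the 14 numbered 37 to 60. Xist, the transcript of the inactive X chromosome, exceeded the summed Y-linked counts in 18 of the first 23 libraries. Y-linked counts exceeded Xist in the other 5 and in all 14 of the later ones. Every group had libraries on both sides, with a single later library for GW in D and for vehicle in DA, so for some genes values within each side are given beside pooled ones.

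Ppara (ENSMUSG00000022383, mm10 chromosome 15, 85734983 to 85802819) encodes PPARα, a fatty acid sensor of the same family as PPARδ. In WT it had 18.1 ± 6.72 CPM in vehicle (SD, n = 5) and 16.5 ± 7.59 CPM under GW (n = 5). In D it had 10.7 ± 5.80 CPM (n = 5) and 16.02 ± 13.997 CPM (n = 3). It had 3.63 ± 2.15 and 3.32 ± 2.22 CPM in A (n = 5 each), and 2.07 ± 1.79 (n = 4) and 3.85 ± 1.66 CPM (n = 5) in DA. Ppara fell in DA against WT in vehicle, with a log2 fold change of -3.04 ± 0.64 (SE; adjusted p = 0.0291, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Within libraries 1 to 36 the change was -2.62, and within 37 to 60 it was -3.56. It missed the threshold without Veh_WT replicate 3, 4 or 5, without the columns with the suffix 2 and with limma-trend. The same comparison in A gave -2.24 ± 0.54 and missed the threshold (adjusted p = 0.0931, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), but it passed with the block for library numbers. Under GW, Ppara also missed it in DA (-2.06 ± 0.55, adjusted p = 0.0654) and in A (-2.18 ± 0.56, adjusted p = 0.156) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Ppard (ENSMUSG00000002250, chromosome 17, 28232700 to 28301474) had 0 to 4 counts in each library, and group means ran from 0.910 ± 1.58 CPM for GW in D (n = 3) to 3.75 ± 2.48 CPM for vehicle in A (n = 5). At this depth a 3′ tag could not check the deletion of Ppard, so whether PPARδ was fully absent in D and DA was left open. Pparg, which encodes PPARγ, had group means of 20.3 to 28.1 CPM.

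The GW effect in WT asked which genes the PPARδ agonist changes when both receptors are present. GW raised 20 genes and lowered none, and many of these genes handle fatty acids, from uptake to oxidation. Angptl4, a secreted inhibitor of lipoprotein lipase, rose from 25.03 ± 7.001 to 98.1 ± 22.2 CPM (SD, n = 5 each), and Plin2, a coat protein of lipid droplets, from 35.95 ± 14.03 to 95.7 ± 31.8 CPM. Acot1, a thioesterase that frees fatty acids from coenzyme A, rose from 9.29 ± 4.86 to 66.2 ± 24.8 CPM.

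Acot1 (ENSMUSG00000072949, chromosome 12, 84009490 to 84018371) changed 6.87-fold, a log2 fold change of 2.78 ± 0.34 (SE; adjusted p = 1.05e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its 16 to 41 counts per GW library all lay above the 2 to 8 counts per vehicle library. Angptl4 (chromosome 17, 33773750 to 33781830) rose by 1.95 ± 0.24 in log2 with 5 of 5 GW libraries above all vehicle libraries (adjusted p = 1.22e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The carnitine carrier Slc25a20 rose by 1.31 ± 0.28, and the oxidation enzymes Eci2 by 1.25 ± 0.17, Acadl by 0.97 ± 0.22, Hadha by 0.95 ± 0.19 and Hadhb by 0.76 ± 0.13. Peroxisomes shorten very long chains, and their carnitine transferase Crot rose by 1.06 ± 0.20 and their transporter Abcd3 by 0.95 ± 0.18. The fatty acid binding protein Fabp1, already at 17625 ± 3538 CPM in vehicle, reached 40022 ± 16530 CPM. Me1, which supplies NADPH for lipid synthesis, rose by 2.14 ± 0.39, the lipase Abhd6 by 1.54 ± 0.20, and the secreted lectin Reg4 by 1.68 ± 0.30. Cpt1a, the entry step of oxidation, had 0.84 ± 0.28 and did not pass (adjusted p = 0.355, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Acadvl at 0.76 ± 0.21, Acaa2 at 0.32 ± 0.16 and the stem cell marker Olfm4 at -0.35 ± 0.28 did not pass either. Pdk4, which limits glucose oxidation, had 0 counts in vehicle and 9 under GW, at least 3.16-fold higher at the floor over the group. The stem cell marker Lgr5 had 0 to 6 counts in each library and was too thinly counted to compare. Fits within libraries 1 to 36 and 37 to 60 called 11 and 14 genes, where Acot1 had 2.82 and 2.77 and Angptl4 2.16 and 1.70, and a fit without a filter called 45.

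**Figure D1:**
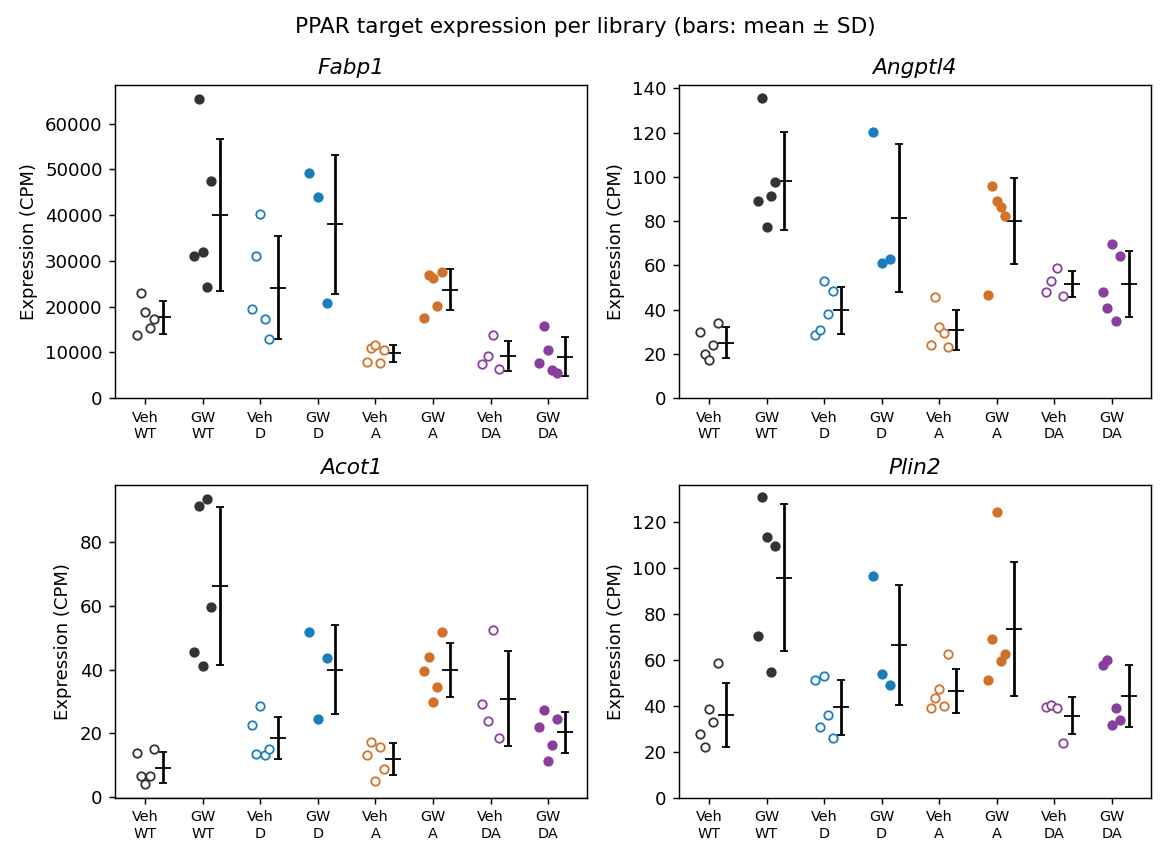
Normalised read count (CPM, y axis) of Fabp1, Angptl4, Acot1 and Plin2 in each library of the 8 groups (x axis), with open points for vehicle, filled points for GW, and bars for the mean ± SD. Acot1 reached 66.2 CPM under GW in WT, 40.0 CPM in D and in A and 20.3 CPM in DA.

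Mitochondrial fatty acid oxidation rose, with 14 of 18 members higher and a median log2 fold change of 0.46 (limma's camera, adjusted p = 5.82e-11, and adjusted p = 0.00449 with an estimated correlation). 5 of its members passed over all genes and 9 adjusted over the list alone. Peroxisomal fatty acid metabolism rose with 11 of 12 members higher (limma's camera, adjusted p = 1.33e-07, and adjusted p = 0.0175 with an estimated correlation), and 2 members passed over all genes and 5 adjusted over the list alone. PPAR targets outside oxidation, which include Angptl4 and the transcription factor Creb3l3 (1.23 ± 0.30), rose with 6 of 8 members higher (limma's camera, adjusted p = 7.12e-07, and adjusted p = 0.00449 with an estimated correlation). 2 of these passed over all genes and 5 adjusted over the list alone. The rest of the calls were lost with an estimated correlation. Fatty acid uptake and binding rose with 5 of 5 members higher (limma's camera, adjusted p = 0.000345, and adjusted p = 0.0618 with an estimated correlation), 1 passing over all genes and 3 adjusted over the list alone. Fatty acid synthesis rose with 7 of 8 members higher, among them Me1 and Scd1 (0.84 ± 0.26), at an adjusted p = 0.000357 by limma's camera and adjusted p = 0.0618 with an estimated correlation. 1 of its members passed over all genes and 3 adjusted over the list alone. Enteroendocrine cell markers, the hormones and granule proteins of gut endocrine cells, rose with 7 of 7 higher (limma's camera, adjusted p = 0.0230, and adjusted p = 0.0618 with an estimated correlation). None of these passed over all genes, and Chgb (0.75 ± 0.26) passed adjusted over the list alone. Oxidative phosphorylation fell by a median of 0.18 in log2, with 43 of 48 members lower (limma's camera, adjusted p = 2.26e-07, and adjusted p = 0.185 with an estimated correlation). Ribosomal proteins fell by 0.12 with 29 of 29 lower (limma's camera, adjusted p = 3.60e-05, and adjusted p = 0.274 with an estimated correlation), and no member of these lists passed over all genes or adjusted over the list alone.

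The remaining 17 lists did not pass in WT, with limma's camera giving adjusted p from 0.0812 to 0.849. They were stem cell, enterocyte, Paneth and goblet cell markers, proliferation, lipid droplets, cholesterol synthesis, glycolysis, mitochondrially encoded transcripts, regenerative epithelium, antigen presentation, xenobiotic metabolism, p53, hypoxia, oxidative stress, the unfolded protein response and the integrated stress response. For 3 lists in WT the signs of median, mean and test differed, and none of these was called. Wnt targets, interferon response and stromal markers had 2, 1 and 1 measured members and were not tested. Tuft and immune cell markers had 50 and 58 counts over all libraries and no measured member.

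The GW effect in D asked what the agonist does in the Ppard knockout. All 20 genes that GW raised in WT lay higher with GW in D too, but none of them passed on its own, and no gene passed for a difference between D and WT. Angptl4 had 39.7 ± 10.7 CPM in vehicle (SD, n = 5) and 81.4 ± 33.6 CPM under GW (n = 3), and Acot1 had 18.5 ± 6.69 and 40.01 ± 14.04 CPM.

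Angptl4 in D had a log2 fold change of 1.02 ± 0.26 (SE; adjusted p = 0.696, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with 1.25 within libraries 1 to 36 and 0.54 within 37 to 60. Acot1 had 1.08 ± 0.37, Plin2 0.75 ± 0.32, Fabp1 0.65 ± 0.32 and Olfm4 -0.73 ± 0.33. Cpt1a had 0.28 ± 0.34, Acaa2 0.21 ± 0.19 and Acadvl -0.05 ± 0.24, whose sign turned to 0.09 within libraries 1 to 36. EdgeR's count of 0 genes stood beside 159 genes at an unadjusted p under 0.05, with a lowest adjusted p of 0.243, and DESeq2 and limma-trend also called 0. The 159 were a smaller share of the 4902 tested genes than the 0.05 expected by chance. The block for library numbers called 1 gene, which that fit also called in WT, and a fit without a filter on low counts called 8. The 20 genes raised in WT all had the same sign in D, with a median of 0.72 against 1.24 in WT. These genes were chosen by their WT values, which favours the WT median. Over the 14 genes raised in A, looked at after the values were seen, the difference between D and WT had a median of -0.59, with a 95% interval below 0 for 7. Whether any PPARδ remained in D was not tested. Peroxisomal fatty acid metabolism rose with 11 of 12 members higher, among them Pex11a (1.58 ± 0.62), which divides peroxisomes (limma's camera, adjusted p = 0.000351, and adjusted p = 0.133 with an estimated correlation). Fatty acid oxidation rose with 15 of 18 higher (limma's camera, adjusted p = 0.00172, and adjusted p = 0.304 with an estimated correlation). PPAR targets outside oxidation rose with 7 of 8 higher (limma's camera, adjusted p = 0.00109, and adjusted p = 0.0983 with an estimated correlation), and 2 members, Angptl4 and Creb3l3, passed adjusted over the list alone. Enteroendocrine cell markers rose by a median of 0.77 with 7 of 7 higher, and this call held (limma's camera, adjusted p = 0.000489, and adjusted p = 0.0111 with an estimated correlation). Its hormone gene Gip (0.93 ± 0.31) passed adjusted over the list alone. Fatty acid uptake, regenerative epithelium and oxidative stress rose, and glycolysis, oxidative phosphorylation, hypoxia and ribosomal proteins fell. In these 7 lists limma's camera gave adjusted p from 0.000464 to 0.0382, which became adjusted p = 0.376 to 0.578 with an estimated correlation.

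The GW effect in A asked what it does in the Ppara knockout. GW raised 14 genes in A, and 12 of them were among the 20 raised in WT, where 0.0571 shared genes would be expected by chance. Angptl4 rose from 30.9 ± 9.03 to 80.1 ± 19.4 CPM (SD, n = 5 each). Fabp1 rose from 9759 ± 1823 to 23683 ± 4527 CPM, and Slc25a20, Hadha, Hadhb and Acadl of fatty acid oxidation rose again. Acaa2, the last enzyme of the oxidation cycle, and the peroxisomal membrane protein Pxmp4 passed in A and not in WT, but their responses did not pass as different between A and WT.

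Eci2 in A changed 2.54-fold, a log2 fold change of 1.35 ± 0.18 (SE; adjusted p = 5.78e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with 1.30 within libraries 1 to 36 and 1.41 within 37 to 60. Acot1 rose by 1.70 ± 0.34, Slc25a20 by 1.52 ± 0.30, Pxmp4 by 1.47 ± 0.33, Angptl4 by 1.38 ± 0.24 and Acaa2 by 0.73 ± 0.16. Acot1, Slc25a20 and Eci2 were higher in each of the 5 GW libraries than in any vehicle library. Plin2 (0.63 ± 0.27), Cpt1a (1.04 ± 0.29), Acadvl (0.83 ± 0.23) and Olfm4 (-0.85 ± 0.29) did not pass. Pdk4 had 0 counts in vehicle and 8 under GW, at least 2.91-fold higher at the floor over the group. The ribosomal pseudogene Rps19-ps6 was called lower, from 276 counts in vehicle to 0 under GW, at least 84.5-fold lower at the floor over the group. Its level is uncertain, since a pseudogene shares sequence with its parent gene, and some libraries of every group of the other genotypes also had 0 counts. Fatty acid oxidation rose with 15 of 18 members higher (limma's camera, adjusted p = 3.99e-19, and adjusted p = 0.000221 with an estimated correlation), 6 passing over all genes and 8 adjusted over the list alone. Fatty acid uptake and binding rose by a median of 0.73 with 5 of 5 higher (limma's camera, adjusted p = 3.62e-07, and adjusted p = 0.0131 with an estimated correlation), 1 passing over all genes and 3 adjusted over the list alone. Peroxisomal metabolism with 11 of 12 higher and PPAR targets with 5 of 8 higher also rose (limma's camera, adjusted p = 7.57e-05 and 0.00324, and both adjusted p = 0.0892 with an estimated correlation), with 1 and 2 members passing adjusted over the list alone. Glycolysis fell with 11 of 12 members lower (limma's camera, adjusted p = 0.00324, and adjusted p = 0.634 with an estimated correlation). Stem cell markers fell by a median of 0.22 with 6 of 9 lower, among them Soat1 (-0.64 ± 0.29) and Aqp4 (-0.82 ± 0.38), at an adjusted p = 0.0101 by limma's camera and adjusted p = 0.303 with an estimated correlation. The 15 calls in A became 3 within libraries 1 to 36 and 11 within 37 to 60, and 19 with a block for the runs of library numbers, which kept all 15, 9 with only the groups compared and 28 without a filter. They became 8 without Veh_A replicate 1, 9 without Veh_A replicate 4, 9 without GW_A replicate 3 and 6 without GW_A replicate 5, and without the last 6 rather than 12 of the WT genes were shared.

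The GW effect in DA asked what the agonist does in the double knockout. None of the 20 genes that GW raised in WT passed in DA, and their changes there went both ways. They ran from a log2 fold change of -0.59 for Acot1 to 0.45 for Hadha, with a median of 0.10. Angptl4 had 51.5 ± 5.76 CPM in vehicle (SD, n = 4) and 51.5 ± 14.9 CPM under GW (n = 5), and Fabp1 had 9183 ± 3280 and 9055 ± 4213 CPM.

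EdgeR called 0 genes in DA, with 157 at an unadjusted p under 0.05 and a lowest adjusted p that rounded to 1.00, where DESeq2 called 1, limma-trend 0 and a fit without a filter 10. The 157 were a smaller share of the 4902 tested genes than the 0.05 expected by chance. Plin2 had a log2 fold change of 0.30 ± 0.31 (SE), with 0.32 within libraries 1 to 36 and 0.61 within 37 to 60. Acot1 had -0.59 ± 0.34, Cpt1a 0.58 ± 0.32, Acadvl 0.11 ± 0.24 and Acaa2 0.08 ± 0.17. Angptl4 at 0.01 ± 0.24 and Fabp1 at -0.02 ± 0.30 changed sign between settings. The 20 genes raised in WT had a median of 0.10 in DA (-0.59 to 0.45), and 14 of them kept their sign. Stem cell markers fell with 8 of 9 lower (limma's camera, adjusted p = 0.0385, and adjusted p = 0.870 with an estimated correlation), and Olfm4, a secreted protein of crypt stem cells, passed adjusted over the list alone at -1.02 ± 0.29. Oxidative phosphorylation fell with 36 of 48 lower (limma's camera, adjusted p = 0.0266, and adjusted p = 0.870 with an estimated correlation).

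**Figure D2:**
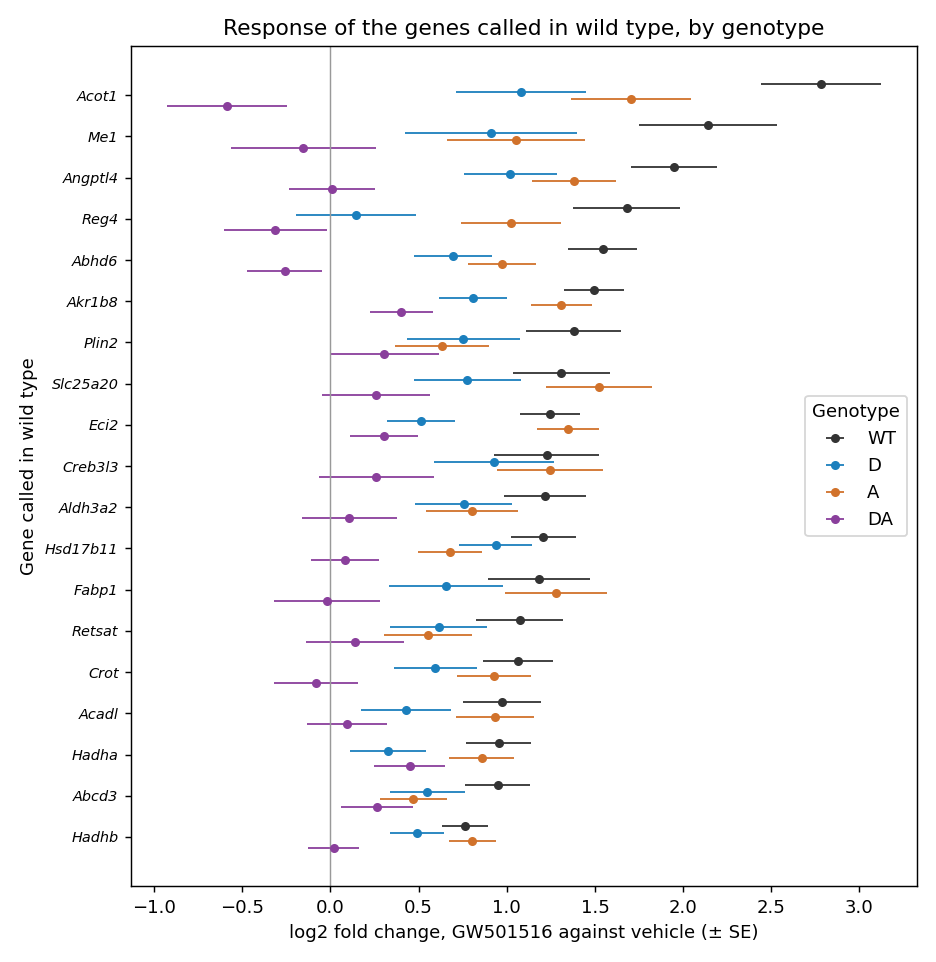
Log2 fold change of GW against vehicle (x axis) for 19 of the 20 genes raised in WT (y axis), with points for the 4 genotypes and bars for ± SE. Over all 20 genes the median was 1.24 in WT, 0.72 in D, 1.00 in A and 0.10 in DA.

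Differences in the GW response between genotypes were tested directly. The response was smaller in DA than in WT for 4 genes, and these were Acot1, Angptl4, Abhd6 and Reg4. Acot1 had 9.29 ± 4.86 and 66.2 ± 24.8 CPM in vehicle and GW in WT (SD, n = 5 each), against 30.9 ± 14.9 (n = 4) and 20.3 ± 6.41 CPM (n = 5) in DA. Reg4, a lectin of secretory cells, had 53.7 ± 13.6 and 173 ± 36.2 CPM in WT against 156 ± 64.8 and 125 ± 24.3 CPM in DA. No gene passed for D or A alone against WT.

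Acot1 differed by -3.37 ± 0.49 in log2 (SE; adjusted p = 0.000166, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with -3.60 within libraries 1 to 36 and -2.59 within 37 to 60. Abhd6 differed by -1.80 ± 0.29 (adjusted p = 0.00065, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Angptl4 by -1.94 ± 0.35 and Reg4 by -1.99 ± 0.42. Of the 20 genes raised in WT, the difference from WT had a 95% interval below 0 for 19 in DA, 8 in D and 3 in A. These genes were chosen by their WT response, which favours intervals below 0 in each knockout. For Acot1 the difference from WT was -1.70 ± 0.52 in D and -1.08 ± 0.51 in A, and DA differed by -2.29 ± 0.48 from A and by -1.67 ± 0.50 from D. EdgeR called 0 genes for D against WT, A against WT, DA against D and DA against A, with 158, 163, 135 and 149 at an unadjusted p under 0.05. Each was a smaller share of the 4902 tested genes than the 0.05 expected by chance. In these comparisons DESeq2 called 0, 0, 1 and 0, and limma-trend 0, 0, 0 and 1. The block for library numbers called 0, 0, 0 and 1, and a fit without a filter 12, 8, 9 and 8. Fits within libraries 1 to 36 and 37 to 60 called 2 and 0 genes for DA against WT. DESeq2 and the block for library numbers called 7 each, the block keeping all 4, and a fit without a filter called 20.

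The response of fatty acid oxidation was lower in DA than in WT for 15 of 18 members, with Hadhb (-0.74 ± 0.20) and Eci2 (-0.94 ± 0.26) passing adjusted over the list alone (limma's camera, adjusted p = 8.34e-05, and adjusted p = 0.100 with an estimated correlation). Peroxisomal metabolism, PPAR targets and fatty acid uptake were lower as well, and ribosomal proteins, which fell in WT, higher (limma's camera, adjusted p = 0.000403 to 0.00491, and adjusted p = 0.0846 to 0.705 with an estimated correlation). Crot (-1.15 ± 0.31) and Fabp1 (-1.20 ± 0.41) passed adjusted over their lists alone. Against A, the oxidation response was lower in DA for 16 of 18 members, with 5 passing adjusted over the list alone, and this call held at the edge of the threshold (limma's camera, adjusted p = 9.93e-08, and adjusted p = 0.04998 with an estimated correlation). Fatty acid uptake, peroxisomal metabolism and enterocyte markers were also lower and glycolysis, which fell in A, higher in DA than in A (limma's camera, adjusted p = 0.000162 to 0.0369, and adjusted p = 0.0972 to 0.654 with an estimated correlation). Against D, the response in DA was lower for peroxisomal metabolism and enterocyte markers and higher for glycolysis and ribosomal proteins, which had fallen in D (limma's camera, adjusted p = 0.0297 each, and adjusted p = 0.7098 to 0.7258 with an estimated correlation). Between D and WT, the oxidation response was lower and that of xenobiotic metabolism higher in D (limma's camera, adjusted p = 0.0156 and 0.0171, and adjusted p = 0.926 and 0.971 with an estimated correlation). Between A and WT the difference was above 0 for oxidative phosphorylation, which fell in WT and was not called in A, with 37 of 48 members higher (limma's camera, adjusted p = 0.0356, and adjusted p = 0.900 with an estimated correlation).

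Each knockout was compared with WT in vehicle to ask how they differ without added agonist. In DA, Acot1 (1.67 ± 0.39) and Reg4 (1.53 ± 0.32) were higher, and Lgals2, an abundant galectin of the gut epithelium, was lower at 4525 ± 1310 CPM (SD, n = 4) against 7902 ± 1364 CPM (n = 5) in WT. Slbp, which binds the ends of histone messages, rose by 0.85 ± 0.20. Among all genes, 2 passed in D, 4 in A and 16 in DA, of which 2, 4 and 6 were pseudogenes.

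Lgals2 in DA had a log2 fold change of -0.80 ± 0.18 (SE; adjusted p = 0.0340, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with -0.81 within libraries 1 to 36 and -0.58 within 37 to 60. H2-Bl, a class I histocompatibility pseudogene on chromosome 17 (36080115 to 36084223), had 3.04 ± 3.39 CPM in WT (SD, n = 5), 39.8 ± 8.44 in D (n = 5), 15.8 ± 14.5 in A (n = 5) and 30.4 ± 12.4 in DA (n = 4), and passed in D (3.59 ± 0.66) and DA (3.22 ± 0.71). The ribosomal pseudogene Rps15a-ps8 had 8.32 ± 8.11 CPM in WT, 259 ± 188 in A and 252 ± 162 in DA. Levels of such pseudogenes are uncertain, since near-identical genes share their sequence. In DA, Hddc3 (3.49 ± 0.78) and Tbc1d23 (1.71 ± 0.40) also rose, and the 16 calls became 15 within libraries 1 to 36 and 8 within 37 to 60. They became 0 without Veh_WT replicate 3, 4 or 5, 5 without Veh_WT replicate 1, 7 without Veh_WT replicate 2, and 5, 3, 6 and 5 without Veh_DA replicates 1 to 4 in turn. They became 0 without the columns with the suffix 2 and 1 with limma-trend. The 4 calls in A became 0 without Veh_WT replicate 1, 3 or 5, 2 without Veh_WT replicate 4, 9 without Veh_A replicate 4 and 10 without Veh_A replicate 5, with 23 and 4 within the library numbers and 13 with the block for them. The 2 calls in D became 1 without Veh_WT replicate 3, 4 or 5 or with limma-trend, and 4 with only the groups compared, with 4 and 0 within the library numbers. Without a filter the calls in D, A and DA were 18, 54 and 80.

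No list passed in D in vehicle, where limma's camera gave a lowest adjusted p of 0.0864, but 4 passed without Veh_WT replicate 4, 2 without Veh_WT replicate 5 or Veh_D replicate 1 or 5, and 1 without Veh_D replicate 2. Regenerative and fetal-like epithelium, genes of wound repair, rose with 8 of 8 members higher in both other knockouts. In DA its median was 0.65, and it included Anxa1 (0.89 ± 0.45) and Ly6a (0.67 ± 0.38) (limma's camera, adjusted p = 0.000429, and adjusted p = 0.805 with an estimated correlation). In A it included Clu (0.99 ± 0.45) (limma's camera, adjusted p = 0.0236, and adjusted p = 0.740 with an estimated correlation). Fatty acid oxidation with 15 of 18 lower, Paneth cell markers with 14 of 15 lower, among them Ang4 (-1.25 ± 0.41), and ribosomal proteins with 23 of 29 lower fell in A (limma's camera, adjusted p = 0.0155 to 0.0382, and adjusted p = 0.740 with an estimated correlation). Oxidative phosphorylation fell in DA with 43 of 48 lower (limma's camera, adjusted p = 0.000429, and adjusted p = 0.805 with an estimated correlation).

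The same comparison under GW, added after the data were examined, asked how the knockouts differ once the agonist is present. DA differed from WT in 41 genes, 29 of them lower, and fatty acid genes that GW raised in WT were among the lower ones. Fabp1 reached 9055 ± 4213 CPM in DA against 40022 ± 16530 CPM in WT (SD, n = 5 each), and Acot1 20.3 ± 6.41 against 66.2 ± 24.8 CPM. In A no fatty acid gene passed.

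Fabp1 differed from WT by -2.14 ± 0.30 in DA (SE; adjusted p = 2.76e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In DA, Acot1 fell by 1.70 ± 0.30, Hsdl2 by 1.65 ± 0.33, Crot by 1.40 ± 0.21, Abhd6 by 1.31 ± 0.19, Eci2 by 1.14 ± 0.17 and Aldh3a2 by 1.14 ± 0.23. Rep15, a recycling endosome protein, and Itch, a ubiquitin ligase, were higher in DA (1.71 ± 0.32 and 1.62 ± 0.31) and in A (1.55 ± 0.32 and 1.68 ± 0.31). Psca, a surface protein of secretory epithelium, rose in DA by 3.54 ± 0.80. H2-Bl passed again in DA (3.78 ± 0.86) and in D, with 34.0 ± 7.34 CPM against 1.25 ± 1.82 CPM in WT, where it had 3 counts in all. Rps15a-ps8 passed again in A and DA. The 41 calls in DA became 20 within libraries 1 to 36 and 38 within 37 to 60, 86 with the block for library numbers, which kept all 41, and 27 with limma-trend. They became 21 without GW_WT replicate 2, 22 without GW_WT replicate 5, 25 without GW_DA replicate 3 and 23 without GW_DA replicate 4. The 9 calls in A became 0 without the columns with the suffix 2, and 5 without GW_A replicate 1 or GW_WT replicate 5 or with only the groups compared. The 3 in D became 1 without GW_D replicate 2, with 19 and 2 in A and 2 and 1 in D within the library numbers. Without a filter the calls in D, A and DA were 17, 58 and 110.

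Fatty acid oxidation fell in DA under GW with 16 of 18 members lower, 2 passing over all genes and 7 adjusted over the list alone (limma's camera, adjusted p = 4.86e-08, and adjusted p = 0.0150 with an estimated correlation). Peroxisomal metabolism fell with 12 of 12 lower and fatty acid uptake with 5 of 5 lower (limma's camera, adjusted p = 7.48e-08 and 1.01e-06, and both adjusted p = 0.0150 with an estimated correlation), with 5 and 2 members passing adjusted over the list alone. Enterocyte markers, which share Fabp1 and Fabp2 with the uptake list, fell with 21 of 25 lower, among them the retinol binder Rbp2 (-0.89 ± 0.22) and the apolipoprotein Apoa4 (-1.09 ± 0.29). That call, at an adjusted p = 3.02e-06 by limma's camera, became adjusted p = 0.140 with an estimated correlation. Regenerative epithelium rose with 8 of 8 higher, with S100a6 (0.75 ± 0.22) and Krt7 (0.62 ± 0.23) passing adjusted over the list alone (limma's camera, adjusted p = 4.14e-06, and adjusted p = 0.153 with an estimated correlation). PPAR targets, fatty acid synthesis and the integrated stress response fell (limma's camera, adjusted p = 0.0139 to 0.0420, and adjusted p = 0.140 to 0.293 with an estimated correlation). In A regenerative epithelium rose with 8 of 8 higher (limma's camera, adjusted p = 0.0280, and adjusted p = 0.874 with an estimated correlation). In D oxidative phosphorylation with 36 of 48 higher and xenobiotic metabolism with 11 of 13 higher rose (limma's camera, adjusted p = 0.0427 and 0.0184, and both adjusted p = 0.916 with an estimated correlation).

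**Figure D3:**
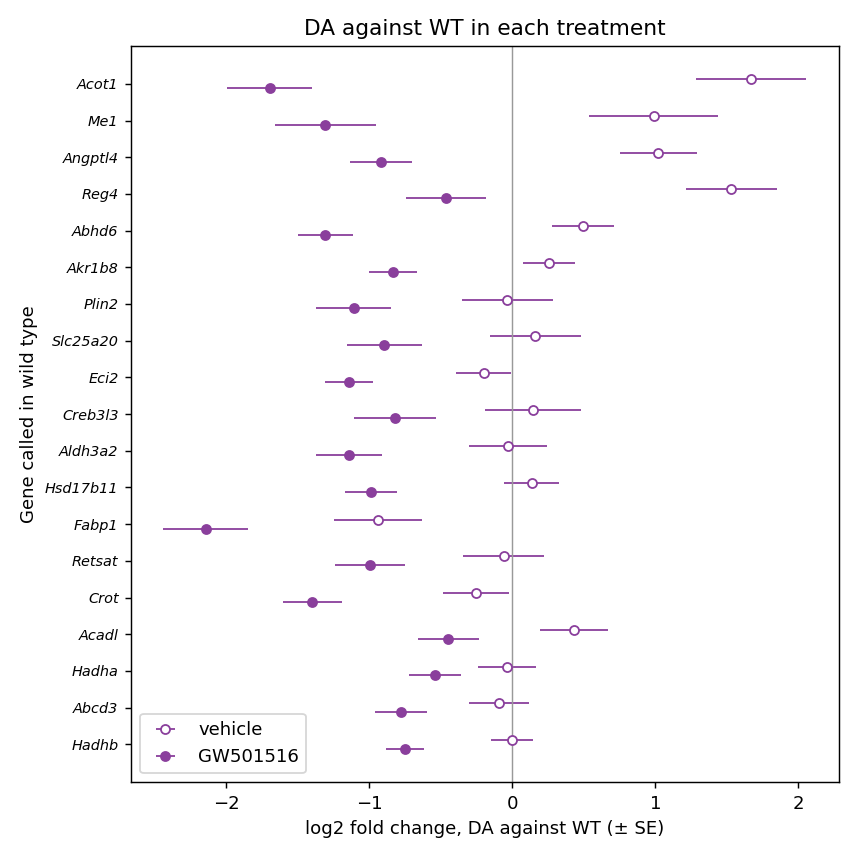
Log2 fold change of DA against WT (x axis) for 19 of the 20 genes that GW raised in WT (y axis), in vehicle (open points) and under GW (filled points), with bars for ± SE. Over all 20 genes the median was 0.14 in vehicle and -0.99 under GW.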

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

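The 3 tests of the smaller GW response in DA were chosen after that result was seen, and the search for libraries far from their group was planned.

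Among 101 groups of library values, 8 held a library far from the others of its group by Dixon's test, where chance alone gives about 1 in 20 groups. In 4 of the 8 a single library had counts and the others had 0, which the test always flags, so these carry no evidence. The stem cell marker Lgr5 had 6.65 CPM in Veh_WT replicate 2 and 2.47 CPM in GW_WT replicate 2, with 0 in the other libraries of each group. Pdk4 had 6.81 CPM in Veh_D replicate 2 and Ppard had 7.70 CPM in GW_A replicate 4, again with 0 in the rest of the group. Angptl4 had 46.7 CPM in GW_A replicate 1, below the 82.2 to 96.0 CPM of the other 4. Plin2 had 124 CPM in GW_A replicate 3, above the others at 51.3 to 68.9 CPM, and 23.9 CPM in Veh_DA replicate 4, below the others at 39.2 to 40.2 CPM. GW_DA replicate 2 had a total count of 395033, below the 479830 to 512122 of the other libraries of its group. No explanation was tested for these libraries.

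In 4 genes the GW response differed between DA and WT by a test of the difference itself, with log2 differences of -3.37 for Acot1, -1.99 for Reg4, -1.94 for Angptl4 and -1.80 for Abhd6. Selection of genes by their WT values was argued against by the 14 genes raised in A, chosen without WT or DA libraries. Their median difference between DA and WT was -1.07 (SD 1.37 over the genes), with 11 of 14 intervals below 0. Between D and WT it was -0.59 with 7 of 14 intervals below 0. Over the 20 genes raised in WT, the median difference was -1.13 on the side of the library numbers where it lay nearer 0. DA lay below WT under GW by a median of -0.99 over the same genes. They were chosen by WT libraries of both sides, which favours both values. The library numbers and a higher vehicle level in DA are therefore not settled by them. In vehicle and under GW, DA differed from WT by 1.67 and -1.70 in Acot1, 1.02 and -0.92 in Angptl4, 0.50 and -1.31 in Abhd6, and 1.53 and -0.46 in Reg4. A higher vehicle level thus made up part of these differences, and that reading stays open. These values are consistent with a response that needs either receptor and is smaller in D, which remains a hypothesis found and tested on the same libraries, and incomplete deletion of Ppard in D or DA and differences of strain or culture between the knockouts were not tested.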

How the results depend on the processing

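The blocks for library numbers and for Xist or Y-linked counts, the fits to part of the library numbers and the fit without the suffix 2 were chosen after the data were seen, and the other settings were planned. No paired analysis was possible because the columns carry no replicate numbers, so the planned replicate block was not run. A block for the runs of library numbers, within which libraries of other groups deviated together (mean correlation 0.185, against -0.038 between runs), was fitted instead. Simulations with the depth, spread and number of these libraries drew genes and libraries independently, without such runs. They recovered 59.6% of genes changed 2-fold in WT and 25.6% for the difference between DA and WT. The cause was not tested for any change below, except that fits to part of the libraries and those leaving out a library hold fewer samples, where a lone library is assumed to vary like the other groups, and that a fit without a filter tests more genes.

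Of 319 values of single genes, 3 fell short of the threshold with RLE size factors, 8 with DESeq2, 29 with limma-trend, 24 with only the groups compared, 30 without the suffix 2 and 5 without a filter. DESeq2, limma-trend and the fit without the suffix 2 each brought 2 past it, the fit to only the groups compared 1 and the fit without a filter 17. The block for library numbers brought 10 past it, Fabp2 in WT and in A, Creb3l3 in A, Hadhb from DA to WT and from DA to A, Ppara in A in vehicle, and Slc25a20, Me1, Apoa4 and S100a6 in DA under GW, and the Xist or Y-linked block 4. Within libraries 1 to 36, 44 fell short, 1 came past and 5 turned sign, and within 37 to 60 these were 60, 5 and 8.

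Without a filter, the calls were 45 for GW in WT, 8 in D, 28 in A and 10 in DA, and 12, 8, 20, 9 and 8 for the differences D to WT, A to WT, DA to WT, DA to D and DA to A. Against WT they were 18 in D, 54 in A and 80 in DA in vehicle, and 17, 58 and 110 under GW. The genes called in WT then had the same sign in 86.7% in D and in A, and 2 were also called in D and 1 in DA. With the block for library numbers, GW in D gave 1 call, the difference DA to WT 7 and DA to A 1, A in vehicle 13 and DA under GW 86. List calls became 3 for A to WT, 9 for DA to D, 8 for A and 5 for DA in vehicle, and 1 for D under GW. Then 1 gene called in WT was also called in D, 96.6% had the same sign in A, and in DA Angptl4 (-0.00020) and Acaa2 (-0.0011) turned sign.

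Within libraries 1 to 36 the calls were 11 for GW in WT, 3 in A, 2 for DA to WT, 4 for D and 23 for A in vehicle, and 19 for A and 20 for DA under GW. Signs turned for Acadvl, Pgk1 and Bnip3 in D (0.093, 0.036 and 0.042), Fabp1 in DA (0.16) and Pex11a from DA to A (0.26). Within libraries 37 to 60 the calls were 1 for A to WT, 0 for DA to WT, 1 for DA to A, 0 for D and 8 for DA in vehicle, and 1 for D and 2 for A under GW. Signs turned for Dbi in WT (-0.020), Acaa1b and Acsl5 in D (-0.42 and -0.085), and Acadvl and Smoc2 in DA (-0.027 and 0.22). They also turned for Dbi from DA to WT (0.070), Abcd3 from DA to D (0.17), and under GW for Ndufa8 in D (-0.16).

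With only the groups compared, GW in A gave 9 calls, D in vehicle 4 and A under GW 5. DESeq2 gave 1 for GW in DA, 7 for DA to WT and 1 for DA to D. Limma-trend gave 1 for DA to A, 1 each for D and DA in vehicle and 27 for DA under GW, and Angptl4 in DA turned to -0.044. Without the suffix 2, DA in vehicle and A under GW gave 0, and Acadvl in DA turned to -0.045. With the Xist or Y-linked block the list calls became 0 for GW in DA, 3 for A to WT, 1 for D and 5 for DA in vehicle and 1 for D under GW, and Fabp1 in DA turned to 0.0099. RLE size factors changed the lists of D under GW to 1.

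With an estimated correlation the list calls became 3 for GW in WT, 1 in D, 2 in A and 0 in DA, 1 for DA to A, 3 for DA under GW, and 0 in each other comparison. Fry kept 7 of the 9 lists for GW in WT and called 1 for GW in D, 2 in A, 0 in DA, 1 for DA to WT, 4 for DA under GW and 0 in the other comparisons whose count changed.

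Leaving out each library in turn gave 6 to 15 calls for GW in A, 1 to 2 for D, 0 to 10 for A and 0 to 7 for DA in vehicle, and 1 to 3 for D, 5 to 10 for A and 21 to 45 for DA under GW. List calls ran from 5 to 12 for GW in D, 6 to 14 in A and 0 to 4 in DA, and from 2 to 7 for D to WT, 0 to 5 for A to WT, 0 to 5 for DA to D and 3 to 6 for DA to A. In vehicle they ran from 0 to 4 for D, 1 to 8 for A and 1 to 7 for DA, and under GW from 0 to 8 for D and 0 to 6 for A. The share of genes called in WT with the same sign ran from 94.7% to 100% in D and 91.7% to 100% in A, and 6 to 12 were also called in A. Genes whose sign turned ranged, under GW against vehicle, from -0.32 to 0.15 for Acadvl, -0.063 to 0.17 for Acsl5, -0.038 to 0.25 for Dbi and -0.54 to 0.016 for Pgk1 in D. In DA they ranged from -0.31 to 0.24 for Fabp1, -0.015 to 0.26 for Acadvl and -0.12 to 0.13 for Angptl4, and in WT from -0.025 to 0.22 for Dbi. Under GW it was -0.18 to 0.89 for Cyp3a11 in D and -0.34 to 0.038 for Scd2 in DA.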

Other observations

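The mean GW effect over the 4 genotypes, the tests of pseudogenes and neighbouring genes, the test of the other stem cell markers, the splits of the D libraries and the splits with the library-number block were chosen after the result was seen.

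Averaged over the 4 genotypes, GW changed 32 genes, 28 higher and 4 lower, and 25 of them had the same sign in all 4. With the block for library numbers 59 genes passed, among them all 32. Beside the fatty acid genes, Mllt3, a reader of acylated histones, rose by 0.93 ± 0.19 (SE; adjusted p = 0.00377, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Cpt1a, which had not passed in any genotype alone, rose by 0.69 ± 0.15 (adjusted p = 0.0142, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The 4 lower genes were Olfm4, Akr1c14, a steroid dehydrogenase (-1.09 ± 0.21), Clec2h, a lectin-like surface protein (-0.54 ± 0.13), and Mpc1, a subunit of the carrier that brings pyruvate into mitochondria (-0.28 ± 0.07). Golgb1, which tethers Golgi membranes, rose by 0.53 ± 0.11. Mllt3, Akr1c14, Clec2h, Mpc1 and Golgb1 were chosen after their values were seen.

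Enteroendocrine cell markers were higher under GW with 7 of 7 members as a mean over genotypes (limma's camera, adjusted p = 0.000269, and adjusted p = 0.00404 with an estimated correlation). Their median rose by 0.36, and the call also held for fatty acid oxidation, peroxisomal metabolism, fatty acid uptake and PPAR targets, which made 5 of the 14 lists called. By genotype, the list was not called in A, with 3 of 7 higher, or in DA, with 6 of 7 higher, and Gip had -0.65 ± 0.28 in A against 0.93 ± 0.31 in D.

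Olfm4, a secreted protein of crypt stem cells, fell with GW by a mean of 0.74 ± 0.15 in log2 over the genotypes (SE; adjusted p = 0.00385, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with -0.35 in WT, -0.73 in D, -0.85 in A and -1.02 in DA. On the side of the library numbers where it lay nearer 0 the mean effect was -0.68, and a block for them gave -0.77. Within libraries 1 to 36 it was -0.78 and missed the threshold (adjusted p = 0.166, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Olfm4 thus fell on both sides. It was called from libraries of both, which favours these values, so the library numbers are not settled by them. A loss of stem cells that lowers all their markers alike was argued against for the measured markers. The other 8 of these had a median of -0.081 with 6 of 8 lower (camera p = 0.217 with an estimated correlation). Only 9 of the 21 listed stem cell markers were measured, Olfm4 among them, and the rest had too few counts. A smaller or partial loss stays open, since Aqp4 had -0.48 ± 0.21 (unadjusted p = 0.0259) and the list with Olfm4 was called lower, with 7 of 9 members lower (limma's camera, adjusted p = 0.0118, and adjusted p = 0.237 with an estimated correlation). Olfm4 was lower in DA as well, so an action of GW outside both receptors is a candidate explanation, and neither this nor incomplete deletion of Ppard was tested.

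The genes called between DA and WT in vehicle held more pseudogenes than the tested genes did. Without Ppara they were 6 of 15, or 40.0%, against 1.59% of the tested genes (two-sided Fisher's exact test, p = 5.98e-08), so tags shared with parent genes may account for these calls, and strain differences within the pseudogenes were not tested. Neighbourhood of the targeted genes could not be settled: 2 of 15, H2-Bl and Lgals2, lay within 20 Mb of Ppara or Ppard (two-sided Fisher's exact test, p = 0.212). Under GW, 6 of the 41 genes called in DA lay there, against 5.75% of the tested genes, and no test was run on this. Psca lies within 20 Mb of Ppara, and Angptl4, whose response differed between DA and WT, within 20 Mb of Ppard. Chance differences of the vehicle libraries alone were argued against, since 14 of the 16 genes had the same sign under GW, in separate libraries, and Reg4 and Acot1 were the exceptions. The labels do not say whether vehicle and GW libraries came from separate animals or cultures. A chance difference between animals or cultures, shared by both treatments, thus stays open. No biological explanation was tested.

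Other splits of the same libraries showed how often other labels gave as many calls. There were 100 per comparison, and 56 where groups of 5 and 3 libraries were split. The splits treat libraries as independent. Yet libraries of a run of numbers deviated together, and the labels do not say whether libraries came from separate animals or cultures. No adjustment was made over the comparisons either, so a small share of splits falls short of excluding chance. For GW in WT the real split alone, 1 in 100, gave as many genes (20, highest other 5). The same held for D, A and DA against WT in vehicle (2, 4 and 16, highest other 1, 3 and 1). The 16 calls in DA became 0 to 7 when a library was left out. It also held for A and DA against WT under GW (9 and 41, highest other 6 and 29). For the mean GW effect it held too (32, highest other 6). For the difference between DA and WT, 2 of 100 splits gave as many as 4, with a highest other of 13. With a block for library numbers 3 of 100 gave as many as 7, with a highest other of 64. Chance cannot be excluded for GW in A, where 6 of 100 splits gave as many as 15, with a highest other of 51. The 5 other splits, with 22 to 51 genes, each put 5 of the 6 A libraries numbered 1 to 36 in the same group, and the next highest gave 2. With the block for library numbers in every fit, 3 of 100 splits gave as many as 19, with a highest other of 22. Labels were exchanged over all libraries of both groups and not within runs. Many of these splits were thus less even over the library numbers than the real one, so this does not exclude chance. Nor can it be excluded for D against WT under GW, where 3 of 56 splits gave as many as 3, with a highest other of 8. With the block 2 of 56 did, which falls short as well. Where no gene was called all splits gave as many: 56 of 56 for GW in D (highest other 0), and 100 of 100 for GW in DA (highest other 1) and for the differences D to WT, A to WT, DA to D and DA to A (highest other 1, 37, 5 and 15). With the block, which was chosen after the data were seen, GW in D gave 1 gene and no other split any. The splits count calls and do not test that gene, so chance is not excluded for it. The unassigned sample was also not ruled out among the 3 GW columns of D. For genes the block changed the reading of no other comparison. The splits with 37, 15 and 13 genes, and with 64 despite the block, exchanged genotype labels within each treatment. Differences between the genotypes can enter such splits, so they do not show a structure of the libraries beyond their groups.

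For the counts of called lists in GW in D, 2 of 56 splits gave as many as 11, with a highest other of 11. Another split thus called as many, and no adjustment was made over the comparisons, so this falls short of excluding chance. This count was fragile, as it fell to 5 without GW_D replicate 3 and to 1 with an estimated correlation or fry, and the unassigned sample was not ruled out among the 3 GW columns. Chance cannot be excluded either for GW in WT (16 of 100 splits, 9 lists, highest other 13), in A (29, 6 lists, highest other 13) or in DA (78, 2 lists, highest other 10). The differences gave 63 of 100 for D to WT (3 lists, highest other 13), 92 for A to WT (1, highest other 12), 31 for DA to WT (6, highest other 13), 56 for DA to D (4, highest other 12) and 36 for DA to A (5, highest other 11). In vehicle they were 100 for D (0, highest other 10), 42 for A (4, highest other 10) and 73 for DA (2, highest other 11). Under GW they were 45 of 56 for D (2, highest other 13), 89 of 100 for A (1, highest other 14) and 15 for DA (9, highest other 13). These splits ignore the library numbers. With the block in every fit, fewer splits gave as many for GW in WT (4 of 100, 12 lists, highest other 13) and in D (1 of 56, 15 lists, highest other 12). These too lack an adjustment over the comparisons. Chance still cannot be excluded for GW in A (6 of 100, 9 lists, highest other 12), and no other verdict on lists or on the medians below changed. For the median response of the 20 genes raised in WT, the real split alone, 1 of 56, gave 0.72 or more in D, and the highest other gave 0.50. In A the real split alone, 1 of 100, gave 1.00 or more, and the highest other gave 0.74. These shares lack an adjustment over the comparisons as well. Chance cannot be excluded in DA, where 10 of 100 splits gave 0.10 or more and the highest other 0.15. With the block the median in D was 0.67 and the highest other 0.65, so the real split stood only narrowly apart.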
